A study of Mus musculus with 137 samples.

How the data were processed

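The series measured polyadenylated RNA in single mouse embryos at the 2-cell stage from the B6129F1 cross, by SmartSeq2 with oligo-dT priming. Zygotes were collected 5 hours after fertilization and cultured in KSOM with no oil cover, since the inhibitor is hydrophobic. From 6 hours after fertilization the medium held either 10 µM SR1848, an inhibitor of the nuclear receptor NR5A2, or 0.1% DMSO, its solvent. The remaining group received SR1848 and an injection of NR5A2 mRNA at 500 ng/µl. Groups and experiments were taken from the sample titles: 29 libraries are labelled DMSO (19 in experiment 1 and 10 in experiment 2), 41 are labelled SR1848 (17 and 24), and 67 are labelled SR1848 with NR5A2 mRNA (27 and 40). Each library is 1 embryo. Embryos of an experiment may share parents, which the labels do not record, so each p measures the spread between embryos.

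Per the submitters' processing notes, reads were demultiplexed with bcl2fastq, trimmed with Trim Galore 0.6.2 and quantified with kallisto 0.46.1, and R 3.5.1 and DESeq2 1.32.0 were used afterwards. The notes list the builds mm10 and hg19, and the part that hg19 played is not given in the sources used here. The deposited count table holds expected counts (kallisto's estimated counts) for 119358 transcript entries, and 26.3% of its values are not whole numbers (tolerance 1e-9). The authors' deposited table of SR1848 with NR5A2 mRNA against SR1848 gives a log2 fold change and an adjusted p-value per transcript, per the file headers. Columns of the count table were matched to samples by the prefix, number and experiment in their names; the prefix C88 was read as SR1848 with NR5A2 mRNA and the prefix ComS as SR1848, from the numbers of columns and the replicate numbers. All columns were used.

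Transcripts were paired with genes through GENCODE M21 (GRCm38, the mm10 build; positions are counted from 1) for 116682 entries and through the authors' deposited table for 892 more. Both sources paired 116631 transcripts, 116581 of them with the same gene identifier. Another 1779 entries, with 0.656% of counts, were not paired, and 5 entries for B1 SINE, B2 SINE, GFP (2 entries) and an Nr5a2 gene sequence, with 0.158% of counts, were kept apart. Estimated counts were summed by gene and rounded to whole numbers for the tests. The sums cover 36097 genes, of which 31435 had a count. The protocol keeps no strand, and kallisto divides reads between near-identical copies, so members of families such as Trim43, Tdpoz and the ribosomal proteins are estimates that share reads. Library totals ran from 100883 to 9317721 counts with a median of 4694340. A library was called low when its total was under 1 in 5 of the median or its detected genes were under 1 in 2 of the median; 7 libraries were low and all stayed in the comparisons. Each SD and SE covers differences between embryos as well as counting error, and the protocol has no molecular identifiers.

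Genes were tested with edgeR 4.0.16 (quasi-likelihood test, TMM scaling, filterByExpr, group and experiment as terms) in R 4.3.3, with Benjamini-Hochberg adjustment over 14507 genes at 0.05. Levels are log2 CPM (counts scaled to the library size) with a prior count of 1. Genes named in the text were chosen by rule: the 10 with the largest fold change in each direction among genes past the threshold, with a mean of at least 3 log2 CPM, the same sign in each experiment and no predicted, Rik or pseudogene symbol, and the 2 to 4 genes with the smallest p in each of 20 gene lists (the 2 most abundant where no member passed). The lists cover 2-cell transcripts, maternal transcripts, early lineage factors, NR5 and other orphan receptors, nucleolus and ribosome biogenesis, ribosomal proteins, proteasome, spliceosome, RNA polymerase II and elongation, DNA replication and cell cycle, DNA repair, p53 targets, heat shock and unfolded protein response, the response to oxidative and xenobiotic stress (the NRF2 list), lipid and sterol metabolism, nuclear-encoded oxidative phosphorylation, mitochondrially encoded mRNAs, and markers of cumulus and granulosa cells, spermatids, and blood and epithelium. In these lists 4 symbols matched no gene. Lists were tested with camera (limma 3.58.1, preset correlation 0.01), with adjustment over the 20 lists, and again with an estimated correlation and with fry.

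Per embryo, the shares of counts from list members were compared by 2-sided permutation tests with 100000 resamples within experiment (smallest possible p 1e-05), on the log2 scale (0.01 was added to measures that hold zeros), in a family of 24 tests with Benjamini-Hochberg adjustment. Genes detected were counted after thinning to 1000000 counts. Return of expression was measured without shared embryos: genes called for SR1848 against DMSO in one experiment were looked up for NR5A2 mRNA against SR1848 in the other. The lists, comparisons, tests, rule for named genes and most alternatives were fixed before the data were examined. The settings without particular libraries, the tests of repeat entries and of the mitochondrial share (both in the family of 24), the test of differences between the experiments, the positions between groups and the correlations with GFP were added afterwards.

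Alternatives were relative log expression, total counts and counts of the maternal list as scaling; DESeq2 1.42.0 and limma-voom; other filters; no experiment term; each experiment alone; a replicate block; transcripts in place of genes; other thresholds; and leaving out low or doubted libraries. The code was tested on simulated data: at the sizes of the SR1848 and DMSO groups it recovered 54.1% of 2-fold and 100.0% of 4-fold changes, with 2.91% unchanged genes among its calls. The simulation gave every gene the same spread, changed few genes and held no libraries that go against their labels. These rates therefore need not hold for the real data. Libraries of a group were checked for copies of each other, and the closest pair (chi-square per gene 15.8) was far above sampling noise. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 made tables and figures. A planned search for NR5A2 motifs near genes was not run, because no genome sequence was at hand.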

Results

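The data are RNA profiles of single mouse embryos at the 2-cell stage, in 3 groups and 2 experiments: 29 labelled DMSO, 41 labelled SR1848 and 67 labelled SR1848 with NR5A2 mRNA. The series title names activation of the zygotic genome by NR5A2, a nuclear receptor that binds DNA, as its subject. Library totals had a median of 4694340 counts. They ran from 100883 to 9317721 in libraries labelled DMSO, from 621489 to 7888072 in those labelled SR1848, and from 145058 to 7828827 in those labelled SR1848 with NR5A2 mRNA. In 7 libraries the total or the number of detected genes was low: DMSO 6, 13 and 16, SR1848 8 and NR5A2 mRNA 22 of experiment 1, and NR5A2 mRNA 27 and 40 of experiment 2.

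Nr5a2 (ENSMUSG00000026398, chromosome 1, 136842571 to 136960448 on GRCm38) was read first, since its mRNA was injected. It averaged 104 ± 49.9 CPM (SD, n = 19) in embryos labelled DMSO of experiment 1 and 16.2 ± 8.68 CPM (SD, n = 41) in embryos labelled SR1848. Embryos labelled SR1848 with NR5A2 mRNA in experiment 1 averaged 2525 ± 2247 CPM (SD, n = 27). In experiment 2 the levels went against part of the labels. Libraries 1 to 8 labelled DMSO had a median of 2281 CPM of Nr5a2 (88.9 to 5474) and 2514 CPM of GFP (47.7 to 7179), while libraries 9 and 10 labelled DMSO had 84.3 and 105 CPM of Nr5a2. Libraries 1 to 8 labelled SR1848 with NR5A2 mRNA had a median of 109 CPM of Nr5a2 (82.0 to 156) and at most 0.456 CPM of GFP, while libraries 9 to 40 had medians of 3136 and 3485 CPM. Because these 16 libraries go against their labels, groups are named as labelled throughout. Every direction that involves DMSO or NR5A2 mRNA is drawn between labels. Counts of all genes called and shares per embryo are also given without the 16 or from experiment 1. Counts of list members are between labels unless another setting is named.

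**Figure D1:**
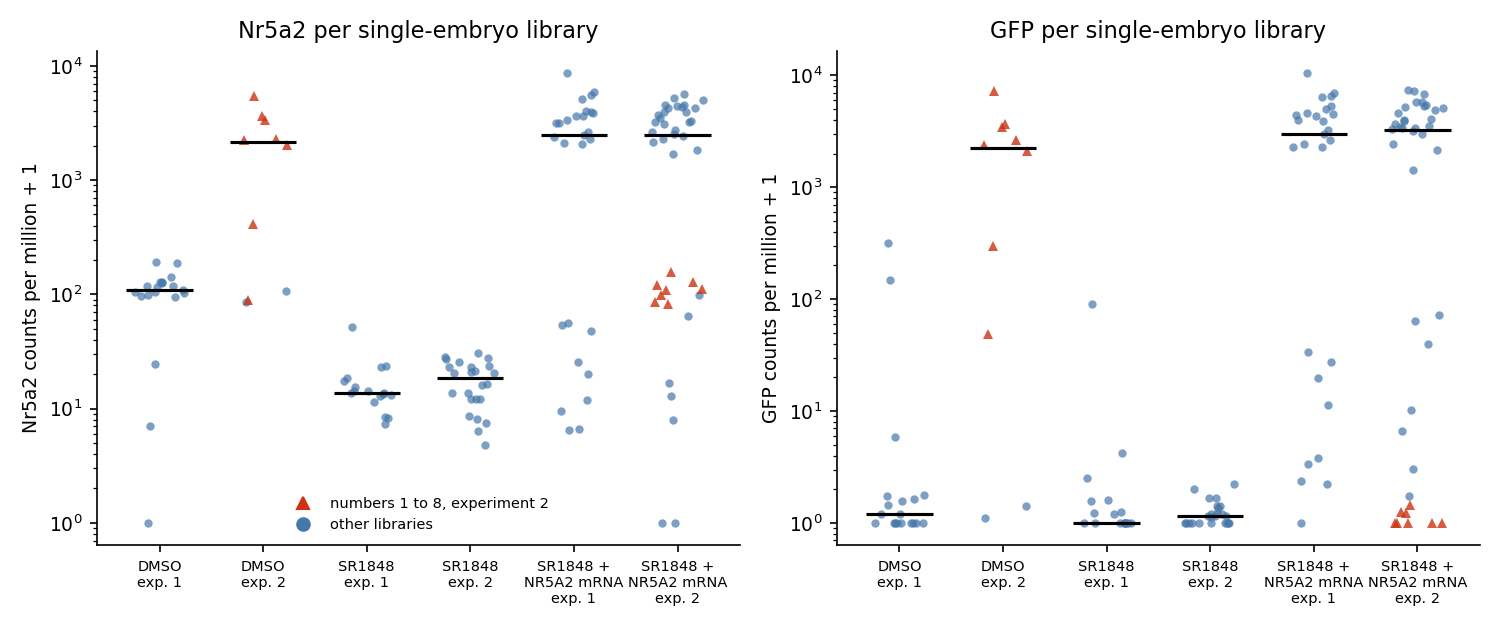
Nr5a2 and GFP in CPM plus 1, on log axes, in each library by label and experiment; black lines are medians and red triangles are libraries 1 to 8 of experiment 2 labelled DMSO or labelled SR1848 with NR5A2 mRNA. The triangles labelled DMSO have a median of 2514 CPM of GFP and those labelled SR1848 with NR5A2 mRNA reach at most 0.456 CPM.

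SR1848 against DMSO asks which transcripts differ when the inhibitor is present from the zygote on. Embryos labelled SR1848 held less mRNA of genes for making ribosomes and more of oocyte transcripts. Of 67 measured genes of nucleolus and ribosome biogenesis 63 fell and none rose, and of 74 maternal transcripts 55 rose and 5 fell. Counts from 2-cell transcripts made up a median of 0.412% in embryos labelled SR1848 and 2.36% in those labelled DMSO, lower in 41 of 41 embryos than the DMSO median (-1.47 ± 0.37 log2, SE; permutation p = 7e-05, adjusted p = 2.8e-04 over 24 tests). That difference was -1.85 without the 16 libraries, -2.52 (permutation p = 1e-05) without the 16 and the low libraries, and -2.01 in experiment 1. It did not pass in experiment 2 (-0.70, permutation p = 0.126). Maternal transcripts made up 5.33% against 2.17% (+1.46 ± 0.29 log2, SE; permutation p = 1e-05, the smallest the resamples can give), higher in 40 of 41 embryos, with +1.74 in experiment 1 and +0.82 in experiment 2. The ratio of 2-cell to maternal counts had medians of 0.0768 and 1.16.

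By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 4796 genes were higher and 5227 lower with SR1848 among 14507 tested. Ctsc, the lysosomal protease cathepsin C (ENSMUSG00000030560, chromosome 7, 88278085 to 88310888), averaged 0.52 ± 2.49 log2 CPM (SD, n = 41) against 7.10 ± 4.74 (SD, n = 29) in DMSO. Its fitted change was -8.76 log2 (SE 0.93, adjusted p = 1.76e-14 by edgeR), and all 41 embryos were below the DMSO median. This was the largest fall among genes that averaged at least 3 log2 CPM and met the rest of the naming rule. Other large falls were those of Ppat, the first enzyme of purine synthesis (-7.97 log2), Pdxk, which activates vitamin B6 (-7.32), and Sumo2, a ubiquitin-like modifier (-7.32). Psat1 of serine synthesis (-6.81), the folate receptor Folr1 (-6.68), Ankrd10 (-6.90) and Tomm5 of the mitochondrial import pore (-6.65) also fell. The tripartite motif genes Trim43c (-7.04) and Trim43a (-6.92), near-identical copies that share reads, fell with them. Nr5a2 itself fell by 5.28 on the log2 scale (SE 0.57), and by 2.58 without the 16 libraries.

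Among the largest rises were those of Psenen, a subunit of gamma-secretase (3.29 log2, SE 0.40), Actn3, an actin cross-linker (3.22), and Dph6 of diphthamide synthesis (3.09). Pdlim2 (2.98), the endoplasmic reticulum protein Wfs1 (3.05) and adenosine deaminase Ada (2.91) also rose, each above the DMSO median in 40 of 41 embryos. F8a (3.29) and the interleukin receptor subunit Il12rb2 (2.83, and 4.83 without the 16 libraries) rose as well. Lman1, a carrier of secretory cargo, had the highest fold (4.23), but 1 low library, SR1848 8 of experiment 1, held 92.2% of its CPM in the group, and without the low libraries the change was 0.75. Tgfbr3, a co-receptor for TGF-beta, moved likewise from 3.19 to 1.44.

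Among lineage factors 5 of 29 rose and 17 fell, including Tead4, needed for trophectoderm (-12.60 log2, SE 1.09, with counts in 4 of 41 embryos labelled SR1848), Dppa4 (-6.62), Zfp42 (-4.40) and Klf5 (-3.70). Of 68 measured 2-cell transcripts 6 rose, 27 fell and the rest passed in neither direction; Trim43b (-6.28), Ubtfl1 (-4.38) and Tdpoz2 (-8.89) fell. Without the 16 libraries 20 of these transcripts rose and 27 fell. Maternal transcripts that rose included Tcl1b2 (2.82), Nlrp9b (2.15) and the oocyte transcription factors Nobox (2.66) and Lhx8 (2.24). Maternal counts are relative to the other transcripts of a library, and scaling to the maternal list centres that list, so it cannot test this rise.

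Genes of the ribosome fell widely. In the nucleolar list Pno1 of small subunit assembly (-5.37 log2, SE 0.54), the RNA polymerase I subunit Polr1e (-5.77) and Nip7 (-2.21) fell. Of 79 ribosomal protein genes 2 rose and 66 fell, such as Rpl39 (-3.39), Rpl21 (-3.44) and Rpl30 (-4.49). Of 39 proteasome genes 4 rose and 28 fell (Psma3 -2.56, Psmb1 -3.95), and of 53 spliceosome genes 2 rose and 39 fell (Lsm8 -5.14, Srsf5 -3.02). RNA polymerase II and elongation genes rose in 9 and fell in 26 of 48 cases, with Polr2k (-5.98) and cyclin T1, Ccnt1 (-2.62), among the falls. Of 54 cell cycle genes 8 rose and 33 fell (cyclin E1, Ccne1, -3.26; the replication factor Gins3, -8.81), and of 44 nuclear oxidative phosphorylation genes 8 rose and 27 fell (Cox4i1 -2.79, Ndufa2 -2.86). Heat shock and unfolded protein genes gave 3 and 18 of 29 (the chaperone cofactor Dnajb9, -6.21), and p53 targets 3 and 11 of 18 (Ei24 -4.17, the p21 gene Cdkn1a -1.90).

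Other lists moved in both directions. DNA repair genes gave 13 higher and 12 lower of 40 (Rad52 2.16, Apex1 -3.58), lipid and sterol genes 9 and 14 of 30 (Sc5d 1.69, Cpt1a -2.09, Scd1 -4.27), NRF2 list genes 7 and 6 of 20 (G6pdx 2.49, Mt2 -2.62), and orphan receptors 7 and 5 of 17 (Rarg -4.79, Nr2c2 -4.98). Scaled to the maternal list, repair genes (4 and 29), NRF2 list genes (1 and 13) and orphan receptors (3 and 10) turned mainly lower. With relative log expression or total counts, repair genes (11 and 14, and 12 and 13) and NRF2 list genes (6 and 8 in both) also did. None of 13 mitochondrially encoded mRNAs passed the test (mt-Cytb -0.32, adjusted p = 0.297 by edgeR), and 13 were lower when scaled to the maternal list. Among markers of other cells, cumulus and granulosa genes gave 3 higher and 1 lower of 12 (Col4a2 2.02, Amhr2 -5.05), spermatid genes 4 and 2 of 7 (Gapdhs 1.98, Ldhc -3.45; 0 and 3 when scaled to the maternal list), and blood and epithelium genes 0 and 5 of 7 (Epcam -2.15). One of the cumulus rises, Sparc (2.20), was -0.49 without the low libraries, which include SR1848 8 of experiment 1.

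By camera with adjustment over the 20 lists, the nucleolar (adjusted p = 1.01e-15), ribosomal (4.66e-13), spliceosome (3.3e-06), proteasome (2.85e-04), polymerase (0.0172), oxidative phosphorylation (0.0172), cell cycle (0.0219), 2-cell (0.0331) and heat shock (0.0497) lists were lower than other genes and the maternal list (2.84e-12) higher. Lineage factors (0.0527) and p53 targets (0.0573) missed the threshold. Each of these calls was lost with an estimated correlation (lowest adjusted p = 0.772 with an estimated correlation), and without the 16 libraries the 2-cell and heat shock calls ended (adjusted p = 0.0664 for both by camera). Medians and camera differed in sign for 6 lists, none of them called: repair, NRF2, orphan receptor, mitochondrial, cumulus and spermatid genes. Adjusted over the list alone, the counts were the same in every list except maternal transcripts (56 higher and 5 lower) and the proteasome (5 and 28).

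Within experiment 1 4941 genes were higher and 4318 lower, within experiment 2 688 and 3015, and without the 16 libraries 5993 and 5012. Scaled to the maternal list 1101 were higher and 9091 lower (10.8% of calls higher against 47.8%), with the median of all genes at -1.40 log2 against -0.06; with relative log expression and total counts that median was -0.26 and -0.18.

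**Figure D2:**
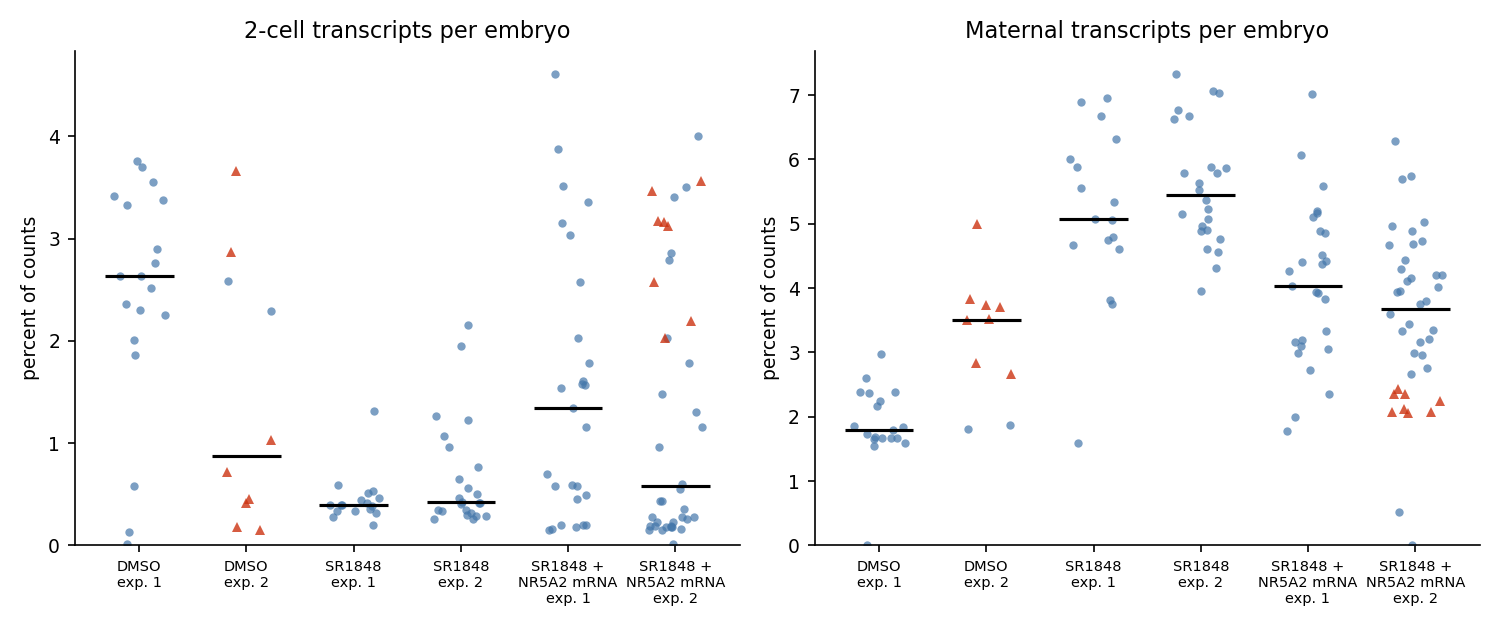
Percent of counts from 2-cell transcripts (left) and from maternal transcripts (right) in each embryo by label and experiment; black lines are medians and red triangles are libraries 1 to 8 of experiment 2 labelled DMSO or labelled SR1848 with NR5A2 mRNA. Embryos labelled SR1848 have medians of 0.412% and 5.33% over both experiments, against 2.36% and 2.17% for those labelled DMSO.

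SR1848 with NR5A2 mRNA against SR1848 asks which transcripts differ when NR5A2 is supplied to embryos in the inhibitor. The labels record no group injected without NR5A2 mRNA. In every comparison with the injected group, injection or foreign mRNA as such therefore cannot be told apart from NR5A2. As a group, embryos labelled as injected held more 2-cell and lineage transcripts than those labelled SR1848, more transcripts for ribosomes, and fewer maternal transcripts. Of 68 measured 2-cell transcripts 39 rose and 2 fell, of 29 lineage factors 18 rose and 1 fell, and of 74 maternal transcripts 1 rose and 33 fell. These counts are between labels. Of all genes called between these labels, 6162 were also tested without the 16 libraries, and 4449 of them kept call and sign. Per embryo the 2-cell share had a median of 0.960% against 0.412% (+0.69 ± 0.25 log2, SE; permutation p = 0.0234, adjusted p = 0.0432), above the SR1848 median in 44 of 67. That share did not pass in experiment 2 (+0.35, permutation p = 0.405) or without the 16 libraries (+0.44, permutation p = 0.145), and in experiment 1 it was +1.18 (permutation p = 0.00662). Maternal counts fell from 5.33% to 3.93% (-0.70 ± 0.17 log2, SE; permutation p = 1e-05), lower in 61 of 67 embryos, with -0.63 without the 16, -0.44 without the 16 and the low libraries, and -0.36 (permutation p = 0.0218) and -0.94 in experiments 1 and 2. The embryos labelled as injected were not alike. In sets drawn after the data were seen, the 42 with at least 100 CPM of GFP, outside the 16 and the low libraries, had median shares of 0.318% for 2-cell transcripts and 0.229% for ribosomal proteins, below the 0.410% and 0.302% of embryos labelled SR1848 outside the low libraries. The 14 under 100 CPM of GFP had 2.41% and 0.868%, and libraries 1 to 8 of experiment 2 had 3.145% and 1.41%. Other shares of the 42 went the other way from embryos labelled SR1848 outside the low libraries. Their medians were 0.249% against 0.201% for nucleolar genes and 4.10% against 5.35% for maternal transcripts. In 2-cell share 5 of the 42 and 7 of the 14 lay above the highest embryo labelled SR1848.

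By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment 4290 genes were higher and 1888 lower with NR5A2 mRNA. Nr5a2 rose by 7.22 log2 (SE 0.58, adjusted p = 4.3e-20 by edgeR), above the SR1848 median in 59 of 67 embryos. The largest rise named was that of Hist2h2be, a histone H2B gene (ENSMUSG00000068854, chromosome 3, 96221119 to 96223738), at 11.12 log2 (SE 1.14). It averaged 6.92 ± 5.34 log2 CPM (SD, n = 67) against -1.44 ± 1.54 (SD, n = 41), and embryos labelled SR1848 had a median of 0 CPM in each experiment. Genes that were lower with SR1848 than with DMSO were among the rises: Ctsc (5.10, SE 0.72), Tomm5 (4.37), Ppat (4.22) and Sumo2 (3.95), of which Ctsc (2.90), Ppat (1.99) and Sumo2 (1.31) were smaller without the 16 libraries. Selenos (3.98) and Dnajb9 (3.85), both tied to the endoplasmic reticulum, and the homeobox genes Crxos (3.80) and Obox8 (3.71) rose too; Selenos was 2.52 and Dnajb9 2.36 without the 16.

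Falls were smaller. Tbc1d19 (-2.08 log2, SE 0.24), Actn3 (-1.98), Wfs1 (-1.96), the dynein-linked Nudc (-1.87), the recombination gene Rad52 (-1.79) and Pabpc1l (-1.78), a poly(A)-binding protein of oocytes, fell. Lman1 (-3.47), Tgfbr3 (-2.06), Bsg (-1.89) and Mospd3 (-1.86) were also called, but SR1848 8 of experiment 1 held most of their CPM in its group. Without the low libraries their changes were -0.21, -0.31, -0.61 and -0.08, and of these only that of Bsg passed the edgeR test. Mos, the meiotic kinase in the maternal list, moved likewise from -4.92 to -0.49.

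Among 2-cell transcripts Btg1 (2.66 log2, SE 0.34), Ubtfl1 (2.86), Slfn4 (3.30) and Tdpoz2 (5.10, and 2.67 without the 16 libraries) rose. Lineage factors that rose included Zfp42 (3.24), Tead4 (6.09, and 2.54 without the 16), Gata2 (2.54) and Nanog (1.94), a regulator of pluripotency, at 4.03 ± 1.77 log2 CPM (SD, n = 67) against 2.39 ± 0.98 (SD, n = 41). The maternal genes Nobox (-1.78), Nlrp9b (-1.29) and Tcl1b2 (-1.52) fell. Of 67 nucleolar genes 48 rose and none fell (Nip7 1.88, Gtpbp4 1.63, the nucleostemin gene Gnl3 1.92), and of 79 ribosomal protein genes 55 rose and 2 fell (Rpl39 2.38, Rpl21 2.27). Of 18 p53 targets 9 rose and none fell (Cdkn1a 1.62, the apoptosis gene Pmaip1 3.06), and of 29 heat shock genes 13 rose and 1 fell (Hspb1 1.82). DNA repair genes gave 6 higher and 13 lower of 40 (Apex1 2.43, Msh6 -1.09), but 15 and 3 when scaled to the maternal list.

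Spliceosome genes gave 24 higher and 4 lower of 53 (Srsf2 1.72, Lsm8 2.79, or 1.78 without the 16 libraries), proteasome genes 21 and 5 of 39 (Psme2 2.19, Psmd2 -1.10), polymerase II genes 16 and 6 of 48 (Polr2l 1.67), cell cycle genes 18 and 6 of 54 (Ccne1 2.05, Ccnb2 -0.95) and oxidative phosphorylation genes 18 and 4 of 44 (Cox7b 2.00, Sdha -1.15). NRF2 list genes gave 9 and 4 of 20 (Mt2 2.52, G6pdx -1.28), lipid and sterol genes 7 and 6 of 30 (Cpt1a 1.70, Msmo1 2.00) and orphan receptors 6 and 1 of 17 (Nr2c1 -1.28). Of 13 mitochondrial mRNAs 9 rose and none fell (mt-Nd6 0.74, mt-Cytb 0.75). Blood and epithelium markers gave 6 higher of 7 and none lower: the globin genes Hba-a2 (2.44, SE 0.37) and Hba-a1 (2.26), which share reads, and the keratins Krt18 (2.99) and Krt8 (3.12) were among them. Cumulus and spermatid markers gave 3 higher and 1 lower each, of 12 and of 7 (Amhr2 2.87, Tssk6 2.39); the cumulus fall was that of Sparc (-1.79), which was 0.50 without the low libraries.

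By camera the maternal (adjusted p = 1.02e-12) and repair (0.00311) lists were lower, and the ribosomal (8.02e-06), nucleolar (2.39e-05), lineage (7.92e-04), blood and epithelium (9.74e-04), p53 (0.00249), 2-cell (0.00331) and heat shock (0.042) lists higher. Each call was lost with an estimated correlation (adjusted p = 0.146 for lineage factors and for blood and epithelium, the lowest, 0.399 for p53 and maternal genes, 0.722 for repair genes, and 0.831 for 2-cell, nucleolar and ribosomal genes, with an estimated correlation). Without the 16 libraries the nucleolar list gave 32 higher and 3 lower and its call ended (adjusted p = 0.0634 by camera), as did that of the heat shock list (0.0745). Blood and epithelium genes were then 7 higher of 10, with adjusted p = 0.0269 with an estimated correlation. Adjusted over the list alone, counts were 42 and 2 for 2-cell transcripts, 19 and 1 for lineage factors, 49 and 0 for nucleolar genes, 1 and 34 for maternal genes, 10 and 0 for p53 targets, 7 and 15 for repair, 22 and 7 for the proteasome, 18 and 6 for polymerase II and 18 and 5 for oxidative phosphorylation, and the same in the other lists. Spermatid markers had a median of 0.30 and a camera direction below 0, without a call.

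Within experiment 1 1813 genes were higher and 694 lower, within experiment 2 4446 and 1720, and without the 16 libraries 3386 and 1590. Scaled to the maternal list 8334 were higher and 467 lower (94.7% of calls higher against 69.4%), with the median of all genes at 0.78 log2 against 0.09.

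**Figure D3:**
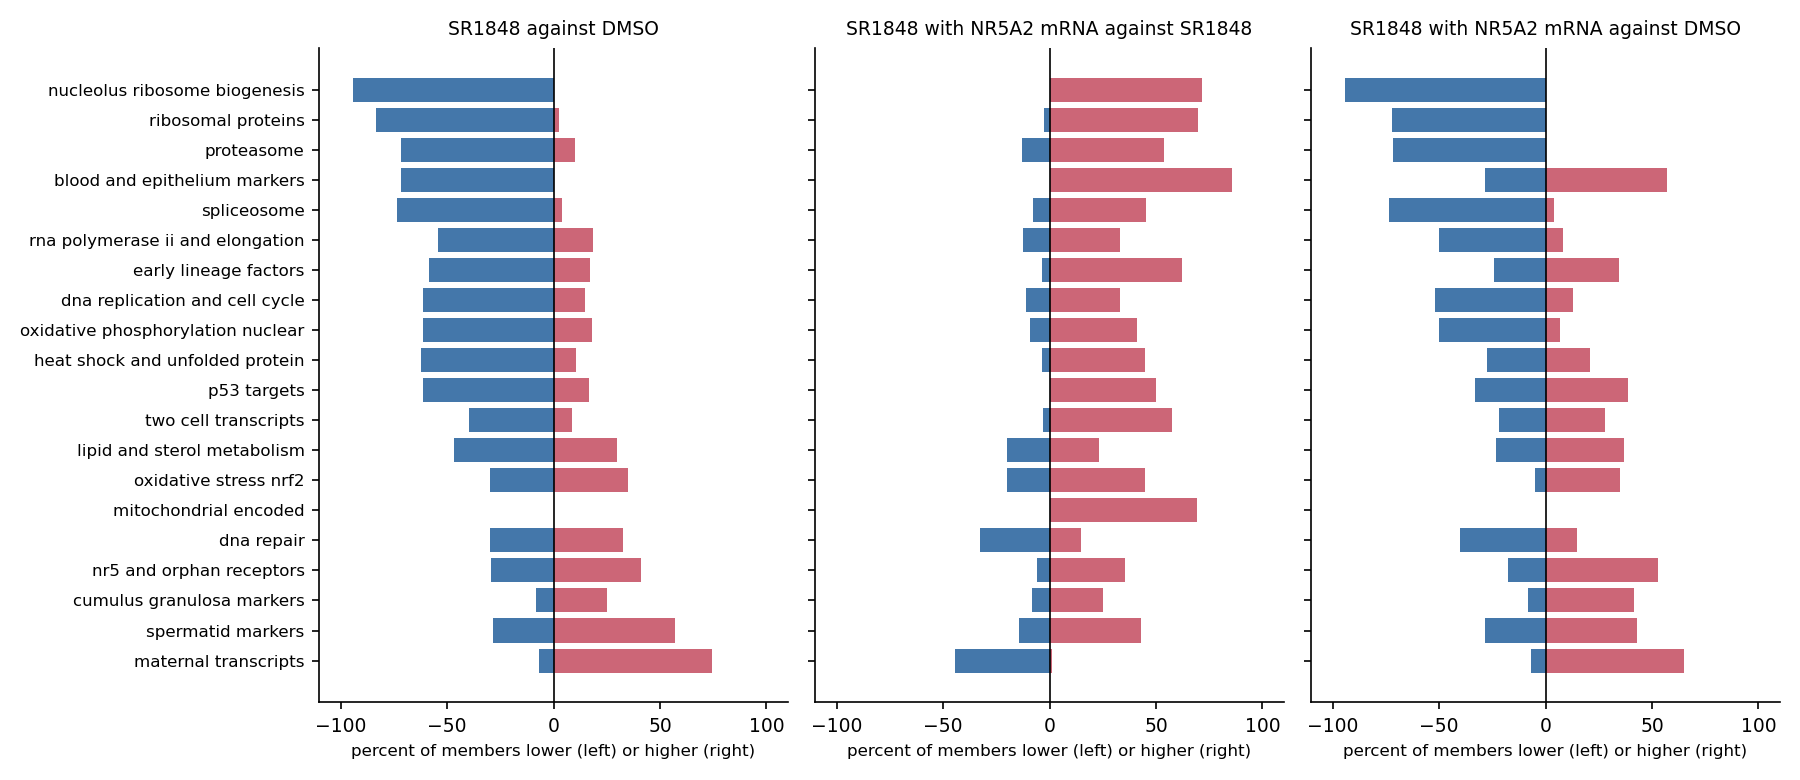
Percent of the measured members of each of the 20 lists that were lower (left of 0, blue) or higher (right of 0, red) past the threshold, in a panel for each comparison. The bars are drawn between labels. Nucleolar genes are lower for 63 of 67 members with SR1848 and higher for 48 of 67 with NR5A2 mRNA against SR1848. Maternal genes are higher for 55 of 74 and lower for 33 of 74. Without the 16 libraries that go against their labels, fewer nucleolar genes were higher with NR5A2 mRNA against SR1848, and that camera call ended.

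SR1848 with NR5A2 mRNA against DMSO asks how far embryos given NR5A2 in the inhibitor still stood from embryos in the solvent. Genes for ribosomes, splicing and protein turnover were lower in embryos labelled as injected than in those labelled DMSO, and maternal transcripts were higher. Of 67 nucleolar genes 63 fell and none rose, of 39 proteasome genes 28 fell and none rose, and of 74 maternal transcripts 48 rose and 5 fell. Maternal counts were 3.93% per embryo against 2.17% (+0.76 ± 0.33 log2, SE; permutation p = 0.0169, adjusted p = 0.0338), higher in 59 of 67 embryos. This was +1.38 in experiment 1 and +1.17 without the 16 libraries, and -0.12 (permutation p = 0.833) in experiment 2. The 2-cell share was 0.960% against 2.36% and did not pass (-0.78 ± 0.42 log2, SE; permutation p = 0.073, adjusted p = 0.117), but passed without the 16 libraries (-1.41, permutation p = 0.0152) and without the low ones (-1.11, permutation p = 0.00574).

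By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment 4458 genes were higher and 3748 lower. These counts come from experiment 1 (5057 and 4044): in experiment 2, where 8 of the 10 libraries labelled DMSO go against their label, edgeR called 0 in either direction, with 330 genes at an unadjusted p under 0.05. Without the 16 libraries 6468 genes were higher and 4484 lower. The rule for naming the largest changes asks for the same sign in experiment 2. There, 2644 of 8190 genes called between these labels over both experiments had the opposite sign. The rule may thus leave out genes with larger changes. Among genes that met it, falls were led by Trim43c (-3.75 log2, SE 0.68, and -5.69 without the 16), Ppat (-3.75), Ankrd10 (-3.71), Pdxk (-3.70) and Ctsc (-3.66). All were named above for SR1848. The thiamine transporter Slc19a3 (-3.64), Vmp1 of autophagy (-3.60; -5.67 without the 16), Psat1 (-3.50), the lipid enzyme Acsl4 (-3.42) and the vitamin B12 receptor Cd320 (-3.40) fell too.

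Fam110a (2.31 log2, SE 0.55), Duoxa2 (2.21), the MAP kinase phosphatase Dusp6 (2.18), Rassf6 (2.18), the orphan receptor Nr2e1 (2.03), the adhesion receptor Selp (2.02), the lysosomal peptidase Tpp1 (1.96) and Senp8 (1.95) rose. Each moved by more than 1.5 times without the 16 libraries, from 3.61 (Tpp1) to 5.63 (Duoxa2). Nr5a2 was 1.94 higher (SE 0.52) between labels and 4.83 higher without the 16. Hist2h2be was 2.24 higher between labels and 13.59 higher without the 16; in the 19 libraries labelled DMSO of experiment 1 it reached at most 0.610 CPM.

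Ribosomal protein genes gave 0 higher and 57 lower of 79 (Rps24 -2.09, Rpl35a -2.18), spliceosome genes 2 and 39 of 53 (Sf3a1 -1.96, Snrpd1 -2.08), polymerase II genes 4 and 24 of 48 (Gtf2f2 -2.47, the cyclin-dependent kinase Cdk7 -1.80), cell cycle genes 7 and 28 of 54 (the helicase subunit Mcm6 -2.03, Cdc25c -2.57) and oxidative phosphorylation genes 3 and 22 of 44 (Atp5a1 -1.82). In the nucleolar list Utp18 (-1.98), Imp4 (-1.84) and Ddx18 (-2.35) fell, and in the proteasome Psma3 (-1.59) and Psmc1 (-1.69). Maternal genes that rose included Npm2, the oocyte nucleoplasmin (1.23, SE 0.25), Tcl1b1 (1.34) and Btg4, an adaptor of maternal mRNA decay (1.28). List members named here were farther from 0 without the 16 libraries, for example Npm2 (2.36), Imp4 (-2.75) and Dppa2 (-3.25). Lineage factors gave 10 higher and 7 lower of 29, with Tead4 (-6.51), Dppa2 (-2.06), Dppa4 (-3.34) and Gata4 (-1.44) among the falls. Of 68 2-cell transcripts 19 rose and 15 fell (Trim43b -3.24, Kdm5b -2.63, Slc16a6 -2.33).

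For several lists the direction depended on scaling. Scaled to the maternal list, lineage factors gave 5 higher and 11 lower, 2-cell transcripts 8 and 26, p53 targets 3 and 8 (7 and 6 in the main test), lipid and sterol genes 3 and 14 (11 and 7 of 30), NRF2 list genes 2 and 7 (7 and 1 of 20), orphan receptors 4 and 6 (9 and 3 of 17) and spermatid markers 1 and 2 (3 and 2 of 7). With relative log expression lineage factors (8 and 10), 2-cell transcripts (17 and 19), p53 targets (5 and 7) and lipid genes (6 and 11) also turned, and with total counts lipid genes did (8 and 9). Named members include Ei24 (-2.22), Sc5d (1.18), Fabp5 (1.12), Nqo1 (1.25), Rora (1.22), Rarg (-2.55) and Odf2 (0.93). Heat shock genes gave 6 higher and 8 lower of 29 (Hspe1 1.05, Hsph1 -1.78), repair genes 6 and 16 of 40 (Neil3 1.06, Parp1 -1.48), cumulus markers 5 and 1 of 12 (Col4a2 1.62) and blood and epithelium markers 4 and 2 of 7 (Hba-a1 1.87, Epcam -1.39). No mitochondrial mRNA of 13 passed (mt-Cytb 0.43, adjusted p = 0.153 by edgeR), while 13 were higher without the 16 libraries.

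By camera the nucleolar (adjusted p = 2.12e-18), ribosomal (6.81e-13), spliceosome (7.06e-09), proteasome (8.89e-08), polymerase (1.81e-04), oxidative phosphorylation (4.64e-04) and cell cycle (7.49e-04) lists were lower and the maternal list (1.29e-06) higher, and each call was lost with an estimated correlation (lowest adjusted p = 0.727 with an estimated correlation). The 2-cell list (adjusted p = 0.305 by camera) had a median of 0.21 and a camera direction below 0, as had lineage factors and p53 targets, none of them called. Adjusted over the list alone, counts were 51 and 8 for maternal genes, 0 and 64 for nucleolar, 0 and 58 for ribosomal, 2 and 42 for spliceosome, 7 and 29 for cell cycle, 5 and 8 for heat shock, 5 and 1 for NRF2, 8 and 7 for p53 and 11 and 8 for lipid genes, and the same in the other lists. Scaled to the maternal list 1460 genes were higher and 6025 lower (19.5% of calls higher against 54.3%), with the median of all genes at -0.47 against 0.21 log2. With relative log expression 3558 were higher and 4526 lower (44.0% of calls higher), with that median at 0.00.

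Return of expression was counted across experiments, so that no embryo labelled SR1848 served on both sides. Of 9225 genes called for SR1848 against DMSO in experiment 1, 3826 (41.5%) were called in the opposite direction for NR5A2 mRNA against SR1848 in experiment 2, where independent calls would give 1811, and 311 in the same direction. Of the 4286 that were lower with SR1848, 2577 (60.1%) were higher with NR5A2 mRNA, and of the 4939 that were higher, 1249 (25.3%) were lower. From experiment 2 to experiment 1 it was 1374 of 3267 (42.1%, with 379.9 by independence), and 58 in the same direction. In experiment 2, 8 of the 10 libraries labelled DMSO and 8 of the 40 labelled as injected went against their labels. Opposite calls may thus partly repeat 1 contrast, and these shares do not by themselves measure return. Without the 16 libraries both shares were smaller, at 1714 of 9252 (18.5%, with 1251 by independence) and 1051 of 5532 (19.0%, with 565.7), beside 645 and 108 called in the same direction. Of the genes higher with SR1848 in experiment 1, 777 were then called in the opposite and 373 in the same direction. The median gene regained 28.4% and 59.9% of its log2 change in the 2 directions, and 8.64% and 15.3% without the 16. Embryos labelled as injected with under 100 CPM of GFP stayed in all these counts, and return was not counted without them. With them and the 16 left out, 3237 of 6045 genes called for NR5A2 mRNA against SR1848 kept call and sign, and 507 changed sign.

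Across genes, which are not independent replicates, the SR1848 change of experiment 1 and the NR5A2 mRNA change of experiment 2 had a correlation of -0.68 (covariance -2.03), and -0.29 (-0.69) without the 16 libraries. From experiment 2 to experiment 1 it was -0.61, and -0.33 without the 16. With embryos labelled SR1848 shared by both comparisons, the correlation on log2 CPM was -0.77, and -0.47 without the 16. In 100 draws with no group effect it ran from -0.83 to -0.14, and from -0.76 to 0.12 without the 16. Both values lie inside those ranges, so the shared correlation cannot tell return from chance. The covariances were -1.29 and -0.96, against simulated means of -0.060 and -0.057. Counts by independence take genes as unrelated.

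**Figure D4:**
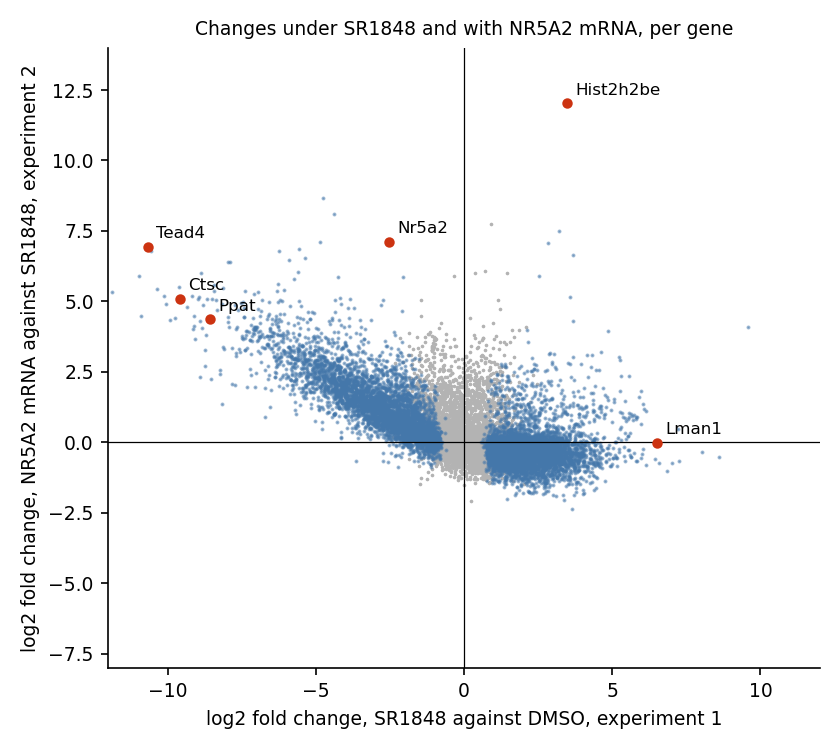
Log2 fold change of each gene for SR1848 against DMSO in experiment 1 (x axis) and for SR1848 with NR5A2 mRNA against SR1848 in experiment 2 (y axis), with genes called for SR1848 in experiment 1 in blue, others in grey and named genes in red. Of the called genes 3826 of 9225 were called in the opposite direction on the y axis, and 1714 of 9252 without the 16 libraries.

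Among the 42 embryos labelled as injected with at least 100 CPM of GFP, outside the 16 and the low libraries, 4 relations with GFP were computed. GFP and Hist2h2be had r = 0.980 and rho = 0.988 (permutation p = 1e-05 each, adjusted p = 2e-05), with r = 0.973 without the 2 farthest libraries and rho of 0.988 (n = 17) and 0.992 (n = 25) within the experiments. GFP and Nr5a2 had r = 0.955 and rho = 0.950. GFP and the 2-cell share had r = 0.116 (permutation p = 0.462) and rho = 0.160 (permutation p = 0.310), with rho of -0.017 and 0.245 within the experiments, and GFP and the maternal share had rho = 0.015.

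After thinning, embryos labelled SR1848 had a median of 12728 genes detected against 14047 with DMSO (-873 ± 345.9, SE; permutation p = 0.00135; -670.2 without the 16 libraries, permutation p = 0.0456, adjusted p = 0.073) and 14203 with NR5A2 mRNA (+1239 over SR1848; permutation p = 1e-05; +1188 without the 16). Mitochondrial mRNAs made up 7.38% of counts with SR1848, 6.07% with DMSO (+0.34 log2; permutation p = 0.477, with +0.82 and permutation p = 0.216 without the 16, +0.57 and permutation p = 0.447 in experiment 1, and -0.49 and permutation p = 0.00585 in experiment 2, lower in 24 of 24) and 9.82% with NR5A2 mRNA (+0.35 over SR1848; permutation p = 0.191, with +0.38 and permutation p = 0.189 without the 16, +0.82 and 0.03 with permutation p = 0.0341 and 0.988 in experiments 1 and 2, and +0.51 with permutation p = 2e-05 without the low libraries).

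The authors' deposited table compares SR1848 with NR5A2 mRNA against SR1848 for 119358 transcripts, with 8560 above 0 and 6243 below 0 past an adjusted p of 0.05. Of 10434 of these that were also tested here at transcript level, 9957 (95.4%) had the same sign here, 6503 were also called here and 56 were called with opposite signs. In the authors' deposited table all 6 Nr5a2 transcripts are above 0, the highest at 8.61 log2, and the GFP entries are at 12.10 and 14.86.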

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

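The test on other histone genes was written before its result was seen; the other tests here were chosen only after the result was seen, for the repeat entries after the authors' values for them were seen.

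In experiment 2, 8 of the 10 libraries labelled DMSO held GFP, a sequence that mouse embryos lack, with a median of 2514 CPM in libraries 1 to 8. Libraries 1 to 8 labelled SR1848 with NR5A2 mRNA held almost none. On genes called between these labels in experiment 1, 16 of the 16 libraries lay nearer the other group than their own, as an exchange of the labels of these 2 sets would give. The 41 libraries labelled SR1848 also lay nearer the NR5A2 mRNA end of this scale (medians 1.01 and 0.968 in experiments 1 and 2), so for the 8 labelled DMSO it shows a likeness to embryos in the inhibitor, and GFP rather than the scale sets them apart from uninjected ones. Outside the 16, the low libraries DMSO 6 and 13 of experiment 1 also held GFP (318 and 147 CPM, from 32 and 49 counts). They lay at 0.70 and 0.78, so such positions are not particular to the 8. The low library SR1848 8 of experiment 1 held GFP too (89.5 CPM), with 50.5 CPM of Nr5a2 and 26.1 CPM of Hist2h2be. Injected mRNA carried over between tubes would change only the injected sequences, but the lowest of the 8 libraries labelled DMSO lay at 0.59 on a scale from DMSO at 0 to NR5A2 mRNA at 1, which argues against it as the whole cause. An exchange of labels may therefore account for the pattern, though it was found and tested on the same data, and no biological explanation was tested.

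Hist2h2be was 11.12 log2 higher with NR5A2 mRNA, more than any other named gene. Over the 42 injected libraries with GFP its counts followed those of GFP with rho = 0.988, as reads of the injected mRNA counted on Hist2h2be would. Libraries with the lowest GFP also had the lowest Hist2h2be: at most 19.2 CPM in 14 libraries under 100 CPM of GFP, against at least 531.5 CPM in the 42. Histone genes switched on together in the embryo would need the other histone genes to rise, by more than 1 log2 as set beforehand. The other 36 had a median of 0.046 log2 with an SD of 0.63, with 4 higher and 1 lower. The bound set beforehand against this explanation, a median under 0, asked too much, since a median below 1 by more than the SD already argues against it; a rise of Hist2h2be alone in the embryo was not tested. Reads of an injected construct may thus account for Hist2h2be, and the sequence of the construct, which would settle it, is not given in the sources used here.

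Among libraries labelled SR1848 with NR5A2 mRNA, outside the 16 and the low ones, 14 under 100 CPM of GFP had higher shares of 2-cell transcripts (median 2.41%, 0.582% to 4.61%) than 42 above it (median 0.318%, 0.146% to 3.88%); no test was run on these sets, which were drawn from the data. Embryos that received no mRNA would look like those labelled SR1848. In Nr5a2 most did, with a median of 17.4 CPM against 13.3 CPM outside the low libraries and 4 of the 14 above the highest library labelled SR1848, and in the 2-cell share 7 of the 14 lay above the highest, at 2.16%. The nucleolar share, which did not serve to draw the sets, had a median of 0.542% in the 14. The highest library labelled SR1848 was at 0.336% outside the low ones (12 of the 14 were above it), and at 0.505% with the low library SR1848 8 of experiment 1 (9 of the 14 were above it). That low library itself held 89.5 CPM of GFP and 50.5 CPM of Nr5a2. Outside the low ones, 5 of the 14 were above the highest library labelled SR1848 in Nr5a2. The nucleolar share argues against the explanation as the whole cause, while it stays open for libraries 2, 7, 8, 12 and 18 of experiment 1, which were not above 0.505%. Embryos of the DMSO group would have its nucleolar share, but the highest of the 14 was 1.22% and the lowest DMSO library outside the 16 and the low ones 1.49%. A gradual loss of the mRNA as an embryo advances stays open: the relation of GFP and 2-cell share (rho = 0.160, permutation p = 0.310) covers the 42 libraries that kept GFP and leaves out the 14, so it decides nothing. What sets these libraries apart stays open, and no biological explanation was tested, as the design names no group for it.

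The effect of the groups differed between the experiments, by an interaction term in edgeR, for 4407 genes for SR1848 against DMSO, 690 for SR1848 with NR5A2 mRNA against SR1848 and 7164 for SR1848 with NR5A2 mRNA against DMSO. Without the 16 libraries these counts were 31, 541 and 0 (529 at an unadjusted p under 0.05 in the last). Experiment 2 then kept only 2 libraries labelled DMSO, so the counts of 31 and 0 rest on little power. Counts on the repeat entries, which the comparisons of genes leave out, were higher with NR5A2 mRNA than with SR1848 by 0.92 log2 for B1 SINE and 1.89 log2 for B2 SINE. In the 10 libraries labelled DMSO of experiment 2 the highest GFP level (7179 CPM) and the highest total (8707715 counts) stood far from the others, among 6 values tested, where chance marks about 1 in 20.

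For SR1848 against DMSO 1 of 60 splits of the libraries within experiment, the real one, called as many genes (10023, highest other 2897). The same held for SR1848 with NR5A2 mRNA against SR1848 (1 of 60, with 6178 and highest other 2179). It also held for SR1848 with NR5A2 mRNA against DMSO (1 of 60, with 8206 and highest other 208). This argues against a chance division of single embryos, though 60 splits cannot show less than 1 in 60. Parents or handling shared within a group were not tested.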

How the results depend on the processing

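The settings without the 16 libraries or without injected libraries of low GFP, and those without the low libraries for lists, shares and named genes, were chosen only after the results were seen; the other alternatives were planned. Counts of genes called stayed within 1.5 times the main count in 91 of 114 cases. Exceptions in genes higher, SR1848 against DMSO, were 1101 scaled to the maternal list, 688 in experiment 2 and 7801 transcripts, and in genes lower, SR1848 against DMSO, 9091 scaled to the maternal list, 8834 with no filter, 3015 in experiment 2 and 9477 transcripts. In genes higher, SR1848 with NR5A2 mRNA against SR1848, they were 8334, 9008 with no filter, 1813 in experiment 1, 6948 transcripts and 2482 without the 16 libraries that go against their labels and injected libraries under 100 CPM of GFP, and in genes lower, SR1848 with NR5A2 mRNA against SR1848, 467, 694 in experiment 1, 1139 with a replicate block, 1161 at an adjusted p of 0.01 and 563 at 2-fold or more. In genes higher, SR1848 with NR5A2 mRNA against DMSO, they were 1460, 0 in experiment 2 and 2454 at 2-fold or more, and in genes lower, SR1848 with NR5A2 mRNA against DMSO, 6025, 0 in experiment 2 and 6432 transcripts. The maternal scaling shifts every gene. The low counts for SR1848 against DMSO in experiment 2 depend on the 16 libraries: without them this comparison gave 2083 higher and 3449 lower there, against 667 and 2600 with them, among genes tested in both experiments. The genes whose change for NR5A2 mRNA against DMSO differed between the experiments went from 7164 to 0 (529 at an unadjusted p under 0.05, by edgeR). Experiment 2 then kept only 2 libraries labelled DMSO, so that fall may also come from low power. For the other exceptions the cause was not tested. Numbers do not pair the embryos: same-numbered embryos were no more alike than others (median r 0.019, 0.015 and -0.026 against 0.019, 0.005 and 0.009), and the block gave 4538 and 4962, 3369 and 1139, and 3269 and 2554 calls.

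By unadjusted permutation p, 40 of 51 values per embryo were the same; after adjustment over 24 tests, genes detected for SR1848 against DMSO also no longer passed in experiment 1 (adjusted p = 0.0719) and without the 16 (adjusted p = 0.073). The 2-cell share was -0.70 (permutation p = 0.126) for SR1848 against DMSO in experiment 2. For NR5A2 mRNA against SR1848 it was +0.35 in experiment 2, +0.44 without the 16 and +0.53 (permutation p = 0.0709) without the 16 and the low libraries. Against DMSO it passed at -1.41 without the 16, -1.11 without the low, -1.99 without both and -1.54 as a ratio to maternal counts, and the maternal share was reversed at -0.12 in experiment 2 (permutation p = 0.833). Unthinned, genes detected differed by -64.4 (permutation p = 0.931) for SR1848 against DMSO and 848 (permutation p = 0.0568) for NR5A2 mRNA against SR1848. The opposite-call share was 18.5% and 19.0% without the 16, 27.6% with shared libraries and 19.9% with split SR1848 libraries, both without the 16.

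Of 540 list values 458 were the same (3 of them the maternal list scaled to itself, which that scaling centres and which show nothing), 24 passed newly, 55 no longer passed and 3 reversed, all in experiment 2: mitochondrial mRNAs (-0.61) and polymerase II genes (-0.54) for SR1848 against DMSO, and mitochondrial mRNAs (-0.37) for NR5A2 mRNA against DMSO. With fry 50 list values were the same and 10 passed newly. With an estimated correlation 33 were the same and 27 no longer passed. Of 2589 values of named genes 2406 were the same, 8 passed newly, 157 no longer passed and 18 reversed. For SR1848 against DMSO Sparc reversed to -0.65 with DESeq2, -1.42 with limma-voom, -0.47 in experiment 2 and -0.49 without the low libraries, and Krt8 to 0.20 without the 16. For NR5A2 mRNA against SR1848 Sparc reversed to 0.49, 1.36, 0.69 and 0.50 under the same alternatives. For NR5A2 mRNA against DMSO in experiment 2 Rps7 (0.22), Rpl37a (0.073), Nelfe (0.24), Sesn2 (0.28), Odf2 (-0.024), Ldhc (0.19), Tssk6 (0.28), Hba-a2 (-0.027) and Ovgp1 (0.25) reversed, each with adjusted p = 1 by edgeR. The low libraries include SR1848 8 of experiment 1, which was not left out alone. In experiment 2, 8 of the 10 libraries labelled DMSO and 8 of the 40 labelled as injected went against their labels. NR5A2 mRNA against DMSO gave 0 calls there, so the reversed signs of genes named for it show no change of direction. Beyond this, the cause of the reversals was not tested. The planned search for NR5A2 motifs was not run for want of a genome sequence. In simulated data with the sizes of the SR1848 and DMSO groups 54.1% of 2-fold changes were recovered, with the same spread for every gene and no libraries against their labels.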

Other observations

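The tests on the repeat entries were chosen only after the files, with the authors' values for these entries, were seen. Short interspersed repeats stood in the count table beside the genes. Embryos labelled SR1848 with NR5A2 mRNA had a median of 31.9 CPM on the B2 SINE entry against 8.23 CPM in those labelled SR1848 (+1.89 log2, permutation p = 1e-05, the smallest the resamples can give), higher in 63 of 67 embryos, with +1.51 in experiment 1 and +2.15 in experiment 2. On the B1 SINE entry the medians were 17.8 and 6.53 CPM (+0.92 log2, permutation p = 0.00509, adjusted p = 0.0122), with +1.20 (permutation p = 0.0479, adjusted p = 0.0719) and +0.72 (permutation p = 0.0468, adjusted p = 0.0936) in experiments 1 and 2, so neither passed alone after adjustment over 24 tests. Against DMSO the B2 SINE entry was +1.76 (permutation p = 0.00566), with +2.78 (permutation p = 1e-05) in experiment 1 and -0.33 (permutation p = 0.646) in experiment 2, and +2.98 (permutation p = 1.4e-04) without the 16 libraries that go against their labels. The B1 SINE entry did not pass against DMSO (+0.74, permutation p = 0.13), with +1.47 (permutation p = 0.0241) in experiment 1, -0.64 (permutation p = 0.261) in experiment 2 and +1.39 (permutation p = 0.0163) without the 16. It passed without the low libraries (+0.63, permutation p = 0.00741) and without the 16 and the low libraries (+1.24, permutation p = 2e-05). For SR1848 against DMSO neither entry passed over both experiments (B2 SINE -0.13, permutation p = 0.819; B1 SINE -0.18, permutation p = 0.702). B2 SINE was +1.27 (permutation p = 0.148) in experiment 1, -2.48 (permutation p = 1e-05) in experiment 2 and +0.92 (permutation p = 0.0964) without the 16, and B1 SINE +0.26 (permutation p = 0.772), -1.36 (permutation p = 2.6e-04) and +0.49 (permutation p = 0.388). Without the low libraries both passed (B2 SINE -0.91, permutation p = 0.00373; B1 SINE -0.69, permutation p = 0.0159), and without the 16 and the low libraries neither did (+0.02, permutation p = 0.947; -0.11, permutation p = 0.724). In the authors' deposited table, for SR1848 with NR5A2 mRNA against SR1848, B1 SINE is at 0.96 (adjusted p = 8.39e-09) and B2 SINE at 2.21 (adjusted p = 4.16e-28, by DESeq2).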
